A study of Homo sapiens with 5 samples.

How the data were processed

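The series is a genome-wide CRISPR knockout screen in OCI-AML2, a human acute myeloid leukaemia cell line. Cells carrying a pooled guide RNA library were kept in 30 nM AZD4320, an inhibitor of BCL2 and BCL-xL (the product of BCL2L1), or in its solvent DMSO until day 14. Guides were then amplified by PCR from genomic DNA and sequenced on an Illumina instrument. There were 2 AZD4320 libraries, 2 DMSO libraries and 1 library of the guide plasmid pool. The title of the last sample names the plasmid while its cell-line label names OCI-AML2, and it was treated here as the plasmid pool. The labels do not say whether replicates were separate cultures, so the spread between these samples may be technical, and p-values cover only these samples.

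The authors deposited raw read counts per guide, not normalized, in 1 table of 90709 guides against 18009 genes. Per the submitters' processing notes, cutadapt, Bowtie2, SAMtools and MAGeCK were used. Their versions, settings and order are not given in the sources used here. Per the file header, both AZD4320 columns carry one lane code, both DMSO columns another and the plasmid column yet another, so lane and treatment cannot be told apart. Each guide identifier names a coding-sequence record, an exon and a genomic position, without naming the build. Of the 90324 guides on the chromosome of their named gene, 10.4% lay inside that gene's span in a GRCh38.p14 RefSeq gene table, so positions are given as the identifiers give them, on a build not given in the sources used here. That table was otherwise used for names only. It held 16691 of the gene symbols, another 1244 matched as older symbols with 1 current symbol, and 74 were not matched.

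Guides with a mean count of at least 20 over the 4 day-14 libraries were kept, which left 84068 guides. Each guide was tested between AZD4320 and DMSO with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling, with no covariate. Genes were then tested in each direction by alpha robust rank aggregation, the ranking idea behind MAGeCK, written for this work. Guides were ranked by one-sided p. The alpha share was set by guides with a one-sided p under 0.25, which came to 0.400 for higher and 0.322 for lower. The null was computed exactly from the distribution of uniform ranks, in place of the permutation null that had been planned. Genes with at least 2 kept guides were tested, 17717 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values given for single genes are from this edgeR and rank aggregation procedure. They measure how far a gene's guides agree in rank within the same 4 libraries, with guides taken as independent. By themselves they do not measure the spread between libraries.

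The size of each effect was given as a gene score. Each guide's log2 CPM (prior count 2) was centred on its mean over the 4 day-14 libraries, and the median over a gene's guides was taken in each library. The gene score is the AZD4320 mean minus the DMSO mean, with a standard error (SE) from limma 3.58.1 over 2 libraries per arm. Gene lists were tested on these library values with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 27 lists. That form sets a list's genes against the other genes, so its p-values do not measure only the spread between libraries. Camera with an estimated correlation and fry were run beside the preset form. With 2 libraries per arm the estimated form has few degrees of freedom, so a list could hardly pass there. A count of list members "adjusted over the list alone" applies Benjamini-Hochberg to that list's genes only. Dropout in culture was the log2 ratio of a day-14 library over the plasmid, as a median over a gene's guides. It has no test, since there is 1 plasmid library.

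The grouping of samples, the tests, the gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule names all genes past the threshold, up to 12 per direction, whose gene scores separated both arms completely. It also allows all members of the BCL2 family, m6A writer and NuRD lists, up to 4 members of every other list with the smallest p, and the 5 genes with the lowest and the 5 with the highest dropout values among genes with at least 4 guides. Some genes that this rule names, and 1 list, are not reported here, although they count in the totals. The planned olfactory receptor list matched 0 genes of the table. Tissue-restricted reference genes, chosen after seeing that, took its place. Alternatives covered the scaling, the guide filter, the tool, the gene-level step, the libraries in the fit, the score's definition and a growth correction. DESeq2 1.42.0 was the other count tool.

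The procedure was tested on simulated counts for the AZD4320 and DMSO comparison, drawn from the real means and library sizes over 17676 genes. It recovered 56% of genes raised 4-fold and 98% of genes raised 8-fold. Lowered genes were recovered less often, with 26% at 4-fold and 74% at 8-fold. With 200 genes changed, 6 unchanged genes were also called, and with none changed 1 gene was called. Camera gave p under 0.05 for 3 of 200 random lists. The simulated guides varied independently, so this does not test camera on lists whose genes vary together. Total counts were between 20313107 and 28908618 per library, and a count of 0 allows a share of at most 1.48e-05% in the shallowest. Reads carry no molecular identifiers, so such limits cover counting error only.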

Results

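Guide abundance was measured by sequencing in 5 libraries of a loss-of-function screen in OCI-AML2 cells. AZD4320 and DMSO were each represented by 2 libraries from day 14, beside 1 plasmid library. A guide that became more frequent under AZD4320 marks a gene whose loss went with survival or growth in the drug, and a guide that became rarer marks the opposite. The design text states this comparison as its purpose, and the series title names the m6A and NuRD complexes. Total counts were 21375057 and 23152937 in the AZD4320 libraries, 28908618 and 20313107 in the DMSO libraries and 27653162 in the plasmid.

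The AZD4320 libraries were far less even than the others. Guides against BAX, which encodes the pore-forming effector of mitochondrial apoptosis, took 0.689% and 0.503% of all AZD4320 counts, against 0.00863% and 0.0145% of DMSO counts. The top 1% of guides held 16.0% and 15.6% of counts under AZD4320, 3.86% and 5.11% under DMSO and 3.44% in the plasmid. The Gini index was 0.722 and 0.706 under AZD4320, against 0.393 and 0.424 under DMSO and 0.353 in the plasmid. The median guide count was 67 and 81 under AZD4320 and 282 and 189 under DMSO, and 5.91% and 4.38% of guides were at 0 under AZD4320 against 2.10% and 2.57% under DMSO. Over 84068 guides, the log2 CPM of the AZD4320 libraries correlated with each other at Pearson's r = 0.478 and Spearman's rho = 0.477, and that of the DMSO libraries at 0.859 and 0.878. These correlations are across guides, which are not independent replicates. One guide against WDR63 held 115169 counts in DMSO replicate 2, or 0.567% of that library.

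**Figure D1:**
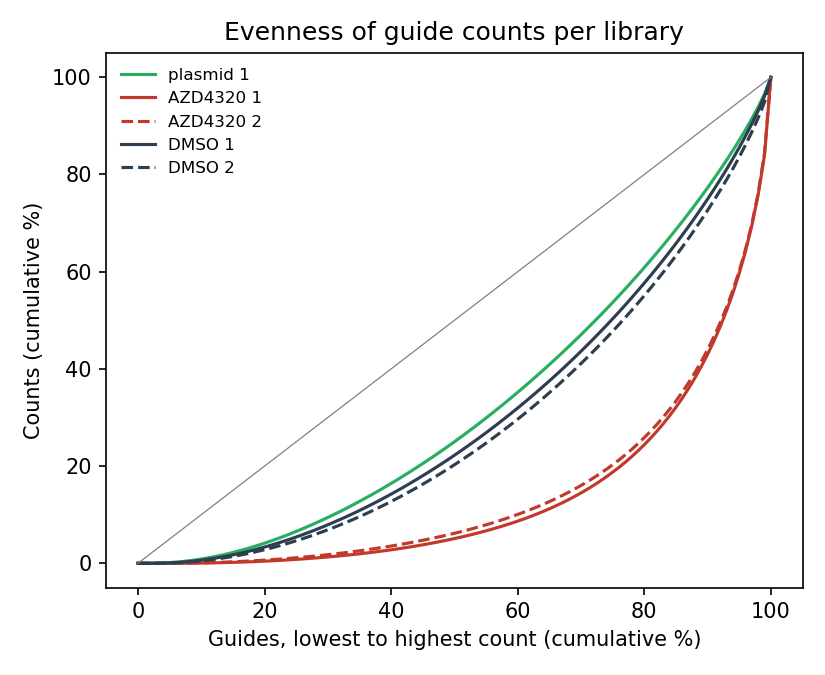
Cumulative share of counts (%, y axis) against guides ordered from the lowest to the highest count (%, x axis), 1 line per library, with the diagonal for perfect evenness. Both AZD4320 lines bend far below the DMSO and plasmid lines, with Gini indices of 0.722 and 0.706 against at most 0.424 in the others.

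In DMSO culture, guides against core cell machinery were lost and guides against a few other genes gained. The lowest values were those of NHP2L1, a spliceosome protein, at -3.93 ± 1.11 (log2 over plasmid, SD, n = 2), and RPL8, a protein of the cytosolic ribosome, at -3.61 ± 0.60 (SD, n = 2). RAN, the nuclear transport GTPase, was at -3.61 ± 0.86, ORC6, of the origin recognition complex, at -3.36 ± 1.08, and MBNL1, a splicing regulator, at -3.34 ± 0.78. Among the highest were HIF1A and ARNT, which form the hypoxia-inducible factor, at 2.58 ± 0.17 and 2.00 ± 1.09, and BAX at 1.62 ± 0.49. In all, 663 of 17789 genes were below -1 in both DMSO libraries and 9 were above 1.

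Essential gene groups separated from reference genes in every day-14 library. The median DMSO dropout was -2.33 for the cytosolic ribosome (66 genes), -1.60 for RNA polymerase II and the spliceosome core (38 genes) and -1.11 for the proteasome (39 genes), each below all 10000 random lists of its size. Members of the mitochondrial ribosome (78 genes) and respiratory complex I (44 genes) had medians of -0.88 and -0.77. Across 143 essential and 139 tissue-restricted reference genes, the area under the ROC curve was 0.938 for the DMSO mean, and 0.930 ± 0.0017 over the single DMSO libraries against 0.890 ± 0.0342 over the AZD4320 libraries (SD, n = 2). Among the drug's targets and their relatives, BCL2 stood at -3.10 ± 0.73 in DMSO, MCL1 at -1.05 ± 0.43 and BCL2L1 at -0.11 ± 0.47. The plasmid has no replicate, so these ratios carry no test.

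Loss of the apoptosis effector BAX gave the largest gain under AZD4320, with a gene score of 6.89 ± 0.50 (log2, SE, n = 2 per arm), and of 5.70 with scaling by total count. All 5 BAX guides were higher, by 6.31 to 7.04 on the log2 scale, and the adjusted p from edgeR and rank aggregation was 7.83e-10. PMAIP1, which encodes the BH3-only protein NOXA, had only 2 guides and rose by 6.77 ± 0.38 (adjusted p = 0.0016, edgeR and rank aggregation). RBM15, a subunit of the m6A writer that methylates adenosines in RNA, rose by 4.33 ± 0.44 with 5 of 5 guides higher. With the planned growth correction, which removes a linear trend on the mean of all 4 day-14 libraries over the plasmid and so contains the AZD4320 values, these 3 genes no longer passed, at 1.35, 2.30 and 2.21.

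Of the genes that rose less, by between 2.28 and 2.99, the highest was WHSC1 (also called NSD2), a histone methyltransferase, at 2.99 ± 0.39, followed by CNOT10, a subunit of the CCR4-NOT deadenylase, at 2.84 ± 0.55, and ZMYND8, a chromatin reader known to bind NuRD, at 2.80 ± 0.38. SYNCRIP, an RNA-binding protein, rose by 2.45 ± 0.38 and DHX36, an RNA and DNA helicase of G-quadruplexes, by 2.44 ± 0.41. MED23, of the Mediator complex, rose by 2.39 ± 0.40 and IRF2BP2, a transcriptional corepressor, by 2.28 ± 0.43. Part of some scores was loss in DMSO. Over the plasmid, IRF2BP2 stood at -1.54 ± 0.58 in DMSO and 0.48 ± 0.83 under AZD4320 (SD, n = 2). ZMYND8 stood at -1.27 ± 0.12 and 1.99 ± 0.34. The other genes named in this paragraph ranged from -0.59 for MED23 to 0.14 for CNOT10 in DMSO. Scaling and the median over guides both enter these ratios. In CPM without scaling, summed over guides, IRF2BP2 averaged 57.2 under AZD4320 against 67.9 in the plasmid. ZMYND8 averaged 69.8 against 39.2. In all, 11 genes passed with more guides under AZD4320 (9 with scaling by total count), all with both AZD4320 libraries above both DMSO libraries. Such separation alone is common, since 48.2% of all tested genes showed it in one direction or the other, against 33.3% by chance.

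Only 2 genes passed as lower under AZD4320. The simulation recovered 26% of genes lowered 4-fold and 74% of those lowered 8-fold, so other losses may have been missed. UBE2J2, a ubiquitin-conjugating enzyme of the endoplasmic reticulum, fell by 3.26 on the log2 scale (SE 0.47, adjusted p = 0.0386 from edgeR and rank aggregation), with 5 of 5 guides lower. PCGF1, a subunit of the noncanonical Polycomb complex PRC1.1, fell by 2.60 (SE 0.37, adjusted p = 0.0084 from edgeR and rank aggregation), with all 4 tested guides lower. Neither call held with scaling by total count, at scores of -4.30 for UBE2J2 and -3.72 for PCGF1, with a mean guide count of at least 100, at -2.88 and -2.61, or with the planned growth correction, at -0.89 and -1.58. The PCGF1 guides gave 0.00739% and 0.00637% of DMSO counts and 0.000473% and 0.000479% of AZD4320 counts. Those against UBE2J2 gave 0.00409% and 0.00374% of DMSO counts and 9.36e-05% and 0.000583% of AZD4320 counts. Counts per UBE2J2 guide ran from 0 to 9 in AZD4320 replicate 1 and from 0 to 77 in replicate 2, so the size of its fall is uncertain. Its least lowered guide was at -0.96 (log2, unadjusted p = 0.358, edgeR). BCL2L1, which encodes the drug target BCL-xL, had all 5 guides lower and a score of -1.91 ± 0.41, and missed the threshold with an adjusted p of 0.137 from edgeR and rank aggregation.

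By the identifiers, the BAX guides lay on chromosome 19 between 49459469 and 49464091 and both PMAIP1 guides on chromosome 18 between 57569887 and 57569937. Those against RBM15 lay on chromosome 1 between 110882143 and 110883459, those against UBE2J2 on chromosome 1 between 1192379 and 1192627, and those against PCGF1 on chromosome 2 between 74733869 and 74734224.

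**Figure D2:**
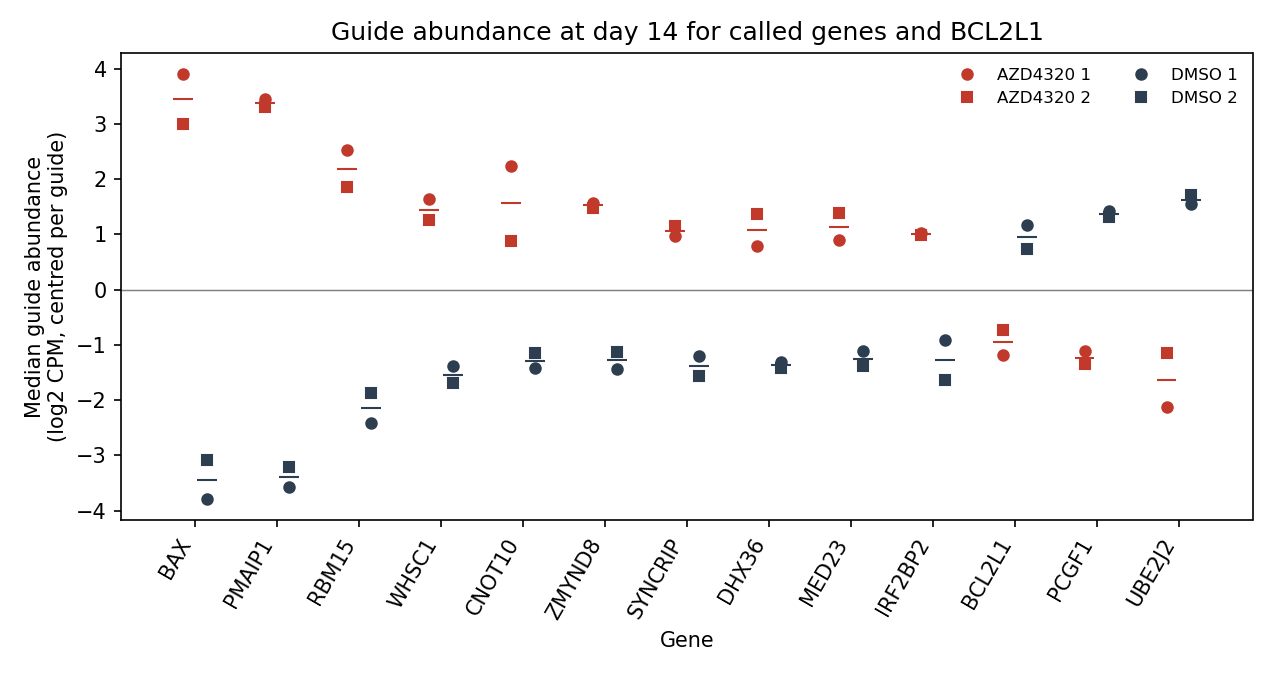
Median guide abundance of each gene (log2 CPM centred per guide, y axis) in the AZD4320 (red) and DMSO (dark) libraries, with circles for replicate 1, squares for replicate 2 and bars for the means, for the called genes reported here and BCL2L1 (x axis). All AZD4320 points lie above all DMSO points for the genes from BAX, with a score of 6.89, to IRF2BP2, with 2.28, and below them for BCL2L1, PCGF1 and UBE2J2.

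No single guide passed at a false discovery rate of 0.05 in edgeR, with 0 higher and 0 lower, while 4536 were higher and 5442 lower at an unadjusted p under 0.05. That split depended on the scaling, with 807 higher and 22602 lower for total count and 5759 higher and 3985 lower for DESeq2 size factors. Without AZD4320 replicate 1 or 2, when the spread came from the DMSO pair, edgeR called 22377 or 24039 guides higher and 15141 or 22194 lower. DESeq2 called 7069 guides higher and 8 lower, and edgeR on counts summed per gene and limma on the gene scores called 0 genes, with 2544 and 2256 genes at an unadjusted p under 0.05. Of the called genes named here, BAX kept its call without any 1 of the 4 libraries, PMAIP1 in 3 of the 4 fits, RBM15 and PCGF1 in 2, IRF2BP2 and UBE2J2 in 1 and the other 6 in 0. The number of genes that rose was 3 without AZD4320 replicate 1, 5 without AZD4320 replicate 2, 4 without DMSO replicate 1 and 6 without DMSO replicate 2, and that of genes that fell was 1, 1, 0 and 2 in the same order.

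Within the BCL2 family, loss of death-promoting members divided into 2 strong gains and little else. BAX and PMAIP1 rose, while BAK1, the other pore-forming effector, had a score of -0.67 ± 0.43, and BBC3 (PUMA) one of -0.31 ± 0.37. BCL2L11 (BIM) had 0.85 ± 0.39 (adjusted p = 0.744, edgeR and rank aggregation), and 3 of the 11 pro-apoptotic members passed with the p-values adjusted over the list alone. The list passed camera as higher (adjusted p = 0.0195), with a median score of 0.05 and a mean of 1.28. With an estimated correlation it did not pass (adjusted p = 0.678 with an estimated correlation), and with scaling by total count its median was -1.13 against -1.29 over all genes. All 5 anti-apoptotic members had negative scores. BCL2L1 was at -1.91 ± 0.41, MCL1 at -1.84 ± 0.49, BCL2L2 at -1.52 ± 0.48, BCL2 at -1.24 ± 0.82 and BCL2A1 at -0.27 ± 0.55. The arms overlapped for BCL2, with library values of -1.77 and 0.67 under AZD4320 and 0.88 and 0.50 under DMSO. They also overlapped for BCL2A1, another member of the anti-apoptotic list, at 0.51 and -0.70 against 0.51 and -0.16. That list fell with a median of -1.52 (camera adjusted p = 0.0153, and adjusted p = 0.678 with an estimated correlation), and 1 member, BCL2L1, passed with the p-values adjusted over the list alone. Both calls were lost without AZD4320 replicate 1, where the medians were 0.31 and -0.95, and without AZD4320 replicate 2, where they were -0.18 and -2.13. Neither list passed with the planned growth correction, at 0.11 and -0.19, or with a mean guide count of at least 100, at 0.02 and -1.45, and the anti-apoptotic call was also lost with scaling by total count, at -2.69. In fry neither list passed, each with an adjusted p of 0.143.

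The list of genes that control the turnover of MCL1, BAX and BAK1 proteins did not pass (median -0.76, camera adjusted p = 0.0902), with 9 of its 13 members negative and 4 positive. UBE2J2 fell, and FBXW7, the substrate receptor of a ubiquitin ligase that targets MCL1, had a score of -1.29 ± 0.38, MARCH5, a mitochondrial ubiquitin ligase, -1.69 ± 0.45 and USP9X, a deubiquitinase, -1.43 ± 0.47. Of the 13 members, 1 passed over all genes and 4 passed with the p-values adjusted over the list alone. The caspase and apoptosome list had a median of -0.04 (camera adjusted p = 0.834), with APAF1 at -0.04 ± 0.56.

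The m6A writer complex was higher under AZD4320 as a group at camera's preset correlation and in fry, but did not pass with an estimated correlation. Beside RBM15, the scores were 1.92 ± 0.57 for METTL14 and 0.79 ± 0.38 for METTL3, which form the catalytic dimer, 0.79 ± 0.46 for WTAP and 1.02 ± 0.64 for KIAA1429 (VIRMA). ZC3H13, RBM15B and CBLL1 were at 0.45 ± 0.42, -0.06 ± 0.59 and -0.13 ± 0.42. Of the 8 members, 1 rose over all genes tested and 3 passed as higher with the p-values adjusted over the list alone. The list's median was 0.79 (camera adjusted p = 0.00257, fry adjusted p = 0.00565, and adjusted p = 0.678 with an estimated correlation). Without AZD4320 replicate 2 the camera call was lost, with a median of 0.41. With scaling by total count the median was -0.37, against -1.29 over all genes.

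Some of the writer's members were also depleted in DMSO culture. METTL14 stood at -2.11 ± 0.31 over the plasmid in DMSO and at -0.07 ± 1.00 under AZD4320 (SD, n = 2). WTAP stood at -1.23 ± 0.08 and 0.01 ± 0.42, and METTL3 at -0.60 ± 0.20 and -0.06 ± 0.36. RBM15 stood at 0.00 ± 0.11 in DMSO and at 4.24 ± 0.80 under AZD4320. Scaling and the median over guides both enter these ratios. In CPM without scaling, summed over guides, WTAP averaged 26.8 under AZD4320, 34.5 in DMSO and 55.8 in the plasmid. In the same order, METTL3 was at 46.9, 45.2 and 64.0, METTL14 at 20.8, 14.4 and 30.3 and RBM15 at 637, 62.0 and 63.9. The return of WTAP, METTL3 and METTL14 to near the plasmid level was therefore not seen in the unscaled means. The readers and erasers of m6A did not pass (9 genes, median -0.23, camera adjusted p = 0.834).

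No member of the NuRD complex, a chromatin remodeller with histone deacetylase activity, passed. Over its 15 members the median was -0.33 (camera adjusted p = 0.857), and 0 passed in either direction with the p-values adjusted over the list alone, by the edgeR and rank aggregation procedure. The scores were -0.33 ± 0.38 for CHD4, the remodelling ATPase, 0.78 ± 0.41 for HDAC1, -0.33 ± 0.37 for HDAC2, -1.20 ± 0.37 for MBD3 and 0.82 ± 0.37 for CHD3. The unadjusted p was 0.0197 for HDAC1 and 0.0266 for CHD3 as higher and 0.00561 for MBD3 as lower, from edgeR and rank aggregation.

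Lists of mitochondrial translation and respiration were lower under AZD4320 at camera's preset correlation, but did not pass in fry. The fry adjusted p was 0.143 for the mitochondrial ribosome, 0.143 for complex I and 0.156 for the cristae and chaperone genes. The mitochondrial ribosome list (78 genes) had a median score of -0.94, with 69 of its 78 members negative (camera adjusted p = 3.82e-09, and adjusted p = 0.678 with an estimated correlation). Examples were MRPL16 at -2.13 ± 0.39 and MRPS16 at -1.58 ± 0.41. With the planned growth correction the list turned to a median of 0.36 and passed as higher (camera adjusted p = 5.65e-07). The axis of that correction contains the AZD4320 values, so a turn in sign does not by itself show a gain. Respiratory complex I (44 genes) had a median of -0.83 with 39 negative members (camera adjusted p = 1.18e-05, and adjusted p = 0.678 with an estimated correlation), among them NDUFC2 at -1.59 ± 0.38. With the growth correction its median turned to 0.43 (camera adjusted p = 3.35e-05). The list of cristae and chaperone genes (20 genes) had a median of -0.59 (camera adjusted p = 0.00922, and adjusted p = 0.678 with an estimated correlation), which the growth correction turned to 0.28 (camera adjusted p = 0.0106), with the inner-membrane organiser IMMT at -1.94 ± 0.57 and the chaperone HSPA9 at -1.57 ± 0.40. No member of the 3 lists passed over all genes, and 3 in each passed as lower with the p-values adjusted over the list alone. The cristae call was lost without AZD4320 replicate 1, at a median of -0.67, and with a mean guide count of at least 100, at -0.34, and its median was -0.999 without AZD4320 replicate 2. The medians compare with -0.13 over all genes.

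The lists of cytosolic translation and messenger RNA synthesis also passed camera as lower at the preset correlation. Their library medians overlapped between the arms, and neither passed in fry. The fry adjusted p was 0.531 for the cytosolic ribosome and 0.592 for RNA polymerase II and the spliceosome core. The cytosolic ribosome had a median of -0.67 over the 52 of its 71 genes left by the count filter (camera adjusted p = 0.00456, and adjusted p = 0.848 with an estimated correlation). RNA polymerase II and the spliceosome core (38 genes) had a median of -0.52 (camera adjusted p = 0.0153, and adjusted p = 0.848 with an estimated correlation). The growth correction, whose axis contains the AZD4320 values, turned these medians to 1.68 and 1.07, and both lists then passed as higher. Examples were RPLP1 at -1.78 ± 0.58 and SF3B2 at -1.70 ± 0.45, and no member passed over all genes. The median library values of the ribosome list were -0.75 and 0.05 under AZD4320 and 0.67 and -0.05 under DMSO. Those of the RNA polymerase II and spliceosome list were -0.67 and 0.02 against 0.50 and -0.05. Both calls were lost without AZD4320 replicate 1, at medians of -0.19 and -0.14, and without DMSO replicate 1, at -0.42 and -0.39. They were also lost with scaling by total count, at -1.73 and -1.63, and with a mean guide count of at least 100, at -0.37 and -0.56. Without AZD4320 replicate 2 the ribosome median was -1.19, and without DMSO replicate 2 the medians were -1.05 and -0.84.

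**Figure D3:**
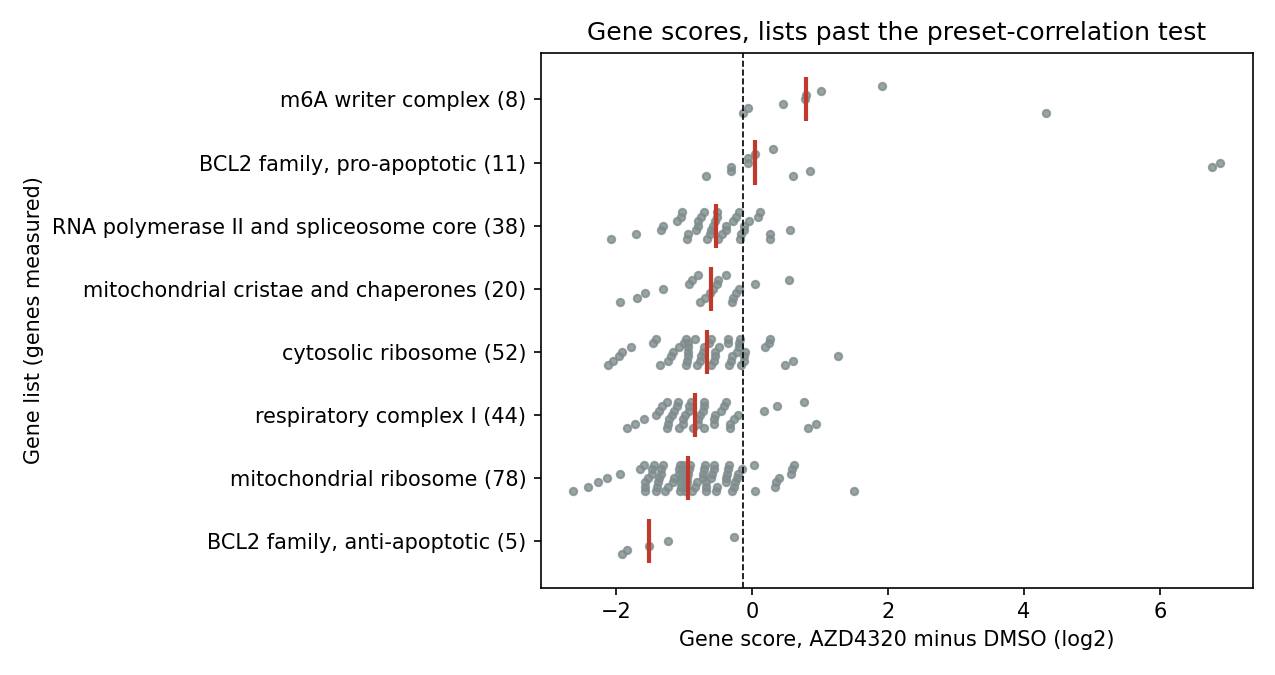
Gene score (log2, AZD4320 minus DMSO, x axis) of each measured gene (grey points) in the 8 lists that passed camera at the preset correlation (y axis, gene numbers in brackets), with list medians as red bars and the median of all genes, -0.13, as a dashed line. The mitochondrial ribosome and complex I points lie mostly left of that line, with medians of -0.94 and -0.83. With scaling by total count the medians of the m6A writer and pro-apoptotic lists lie below 0, at -0.37 and -1.13, where that of all genes is -1.29.

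The remaining lists did not pass camera. Among signalling genes, the mTORC1 inhibition list, whose members restrain the growth kinase, had a median of -1.06 (adjusted p = 0.198), with NPRL2 at -1.39 ± 0.39, and the mTORC1 activation list one of -0.54 (adjusted p = 0.19). RAS, MAPK and PI3-kinase genes had a median of -0.43 (adjusted p = 0.34) and their negative regulators one of -0.13 (adjusted p = 0.834). The integrated stress response list had a median of -0.71 (adjusted p = 0.198) and the proteasome one of -0.56 (adjusted p = 0.11). Among chromatin lists, PRC2 had a median of -0.62 (adjusted p = 0.626), SWI/SNF -0.29, SAGA -0.16, LSD1 and CoREST -0.02 and the menin and MLL list -0.18. The Mediator kinase module had a median of 0.10 (adjusted p = 0.34), myeloid transcription factors one of -0.11 and drug efflux transporters one of 0.58 (adjusted p = 0.601).

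The gene score was next set against growth effects, since a culture that divides less keeps more guides against growth genes. Across 17711 genes, Spearman's rho between the gene score and the mean of all 4 day-14 libraries over the plasmid was 0.695. Against DMSO over the plasmid it was 0.0575, and against AZD4320 over the plasmid 0.817. Keeping more guides against growth genes under the drug would give a negative rho against DMSO over the plasmid. The AZD4320 libraries, whose spread was larger, enter both axes in the planned form. Genes are not independent replicates, so no p is given.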

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

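The scaling on tissue-restricted reference genes, the removal of a trend on DMSO dropout and the growth relation against single DMSO libraries were chosen after seeing the data. The scaling on olfactory receptors was not run, since the table holds none. Where the text gives no cause, the cause was not tested. Scaling by total count moved the median gene score from -0.13 to -1.29 and left 9 genes higher and 0 lower, and 3 lists lower, while size factors of DESeq2 moved it to 0.03 and kept all 11 and 2 genes. A mean guide count of at least 100, which tests fewer guides, left 4 genes higher and 0 lower, and 1 list higher and 2 lower. With DESeq2 per guide, 5 genes were higher, and 7069 guides higher and 8 lower. Counts summed per gene and limma on gene scores each gave 0 genes in both directions. With the estimated correlation 0 lists were higher and 0 lower, and with fry 1 and 0. The smallest unadjusted camera p with the estimated correlation was 0.0642, for the m6A writer complex.

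The planned growth correction, a linear trend on the mean of all 4 libraries over the plasmid, gave 187 genes higher, 4 of them among the 11, and 3 lower, 0 of them among the 2, with 12 lists higher and 1 lower. BAX at 1.35, PMAIP1 at 2.30, RBM15 at 2.21, PCGF1 at -1.58 and UBE2J2 at -0.89 no longer passed. METTL14 at 3.13, PSMB4 at 3.36 and HIF1A at -3.55 newly passed. It turned ACTL6A to 2.59 and ARNT to -2.22, and the medians of the cytosolic ribosome to 1.68, RNA polymerase II and spliceosome 1.07, SWI/SNF 0.74, mTORC1 activation 0.71, proteasome 0.45, complex I 0.43, mitochondrial ribosome 0.36 and cristae genes 0.28. That axis contains the AZD4320 values themselves. A trend on DMSO dropout alone left 10 genes higher, all among the 11, and 1 lower. The growth rho was 0.0575 against DMSO, 0.817 against AZD4320, and 0.0567 and 0.157 with the axis from 1 DMSO library and the score against the other. The ROC area was 0.933 with a plasmid count of at least 100.

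Leaving out 1 library, with the lone sample of an arm assumed to vary like the other arm, gave 3 to 6 genes higher, 0 to 2 lower, 0 to 3 lists higher and 2 to 8 lower. The turnover list newly passed with no guide filter (-0.80) and without DMSO replicate 2 (-0.77), and the Mediator kinase module without DMSO replicate 1 (0.18). The proteasome list newly passed without DMSO replicate 2 (-0.55), with the mean over guides (-0.59) and without the DMSO dropout trend (-0.59). Guides ranged from 0 to 24039 higher and from 0 to 22194 lower, the many calls coming when the spread was estimated from the DMSO pair. The ROC area ranged from 0.929 to 0.931 and the growth rho from 0.568 to 0.762. Replicate numbers are shared between arms but nothing says that they pair the samples, and the deviations of same-numbered libraries correlated at -0.0262. With the replicate number as a block, 9 genes were higher, 8 of them among the 11, 2 were lower, and 9 guides were higher. CCNC newly passed with that block (adjusted p = 0.00164, edgeR and rank aggregation). Over 19 alternatives, the 12 called genes reported here lost their call in 90 of 228 values, from 3 for BAX to 11 for MED23. Among these alternatives, the mean over guides, the prior count of 5 and the gene threshold of 0.1 could not lose a call by construction. The share of lost calls is therefore understated.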

Other observations

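The patterns below were picked after the gene and list results were seen, and each test was written down before it was run, with the matching on single DMSO libraries set after the growth relation was known. None of 6 genes that act in sulfur transfer to the wobble uridine of transfer RNAs passed. The scores were 2.33 ± 0.48 for CTU1, 2.29 ± 0.44 for MOCS3, 2.08 ± 0.40 for CTU2 and 1.62 ± 0.38 for URM1 (SE), and the adjusted p from edgeR and rank aggregation was 0.367 for CTU1 and URM1, 0.395 for MOCS3 and 0.42 for CTU2. NFS1 and TRMU had scores of -0.43 and -0.74. These genes were singled out after their values were seen. CCNC and CDK8, the cyclin and kinase of the Mediator kinase module, had scores of 2.24 ± 0.89 and 2.19 ± 0.54. They did not pass over all genes, and both passed with the p-values adjusted over the module's list alone.

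Genes that gained in DMSO did not all gain further under the drug. HIF1A stood at 2.58 ± 0.17 over the plasmid in DMSO (SD, n = 2) and at 0.64 ± 0.64 under AZD4320. ARNT stood at 2.00 ± 1.09 and 2.08 ± 1.21, and BAX at 1.62 ± 0.49 and 8.36 ± 0.46, in the same order. The gene score of HIF1A, -1.82 ± 0.47 (SE), did not pass in the main fit, and passed as lower with the planned growth correction, as did that of ARNT. ABCC1, a drug efflux pump, had a score of -1.92 ± 0.45 and ABCC10 one of 1.47 ± 0.38, neither of which passed.

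The lower values of the mitochondrial ribosome and complex I lists were set against explanations from guide abundance and from growth. Lists of the same size were matched on log2 CPM or on dropout in 1 DMSO library, and scored against the other. The mitochondrial ribosome lay at percentile 0 of 10000 lists matched on abundance and at most at 0.01 of those matched on dropout, and complex I at most at 0.12 and 0.02. This argues against loss of rare guides and against dropout of growth genes in general as the whole cause. The lists matched on abundance were more abundant than complex I in the other library, at 2.05 against 1.86 and 2.07 against 2.06 (log2 CPM). For the mitochondrial ribosome this held 1 way round, at 1.98 against 1.87, but not the other, at 2.00 against 2.02. A part of the difference may therefore come from abundance. The lists matched on dropout in 1 library had weaker dropout in the other, both ways round, at -0.73 against -0.98 and -0.63 against -0.78 for the mitochondrial ribosome and -0.59 against -0.88 and -0.52 against -0.78 for complex I, so a part of the difference may come from dropout. Removing a trend on DMSO dropout left both calls, at medians of -1.01 and -0.91, while the planned growth correction, whose axis contains the AZD4320 values, turned both. An effect of the drug on cells lacking mitochondrial translation and a difference between sequencing lanes stay open too, as lane and treatment cannot be told apart.

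For the m6A writer, the other 7 members without RBM15 gave an unadjusted camera p of 0.00715 as higher at the preset correlation. With an estimated correlation the camera p was 0.109. Of these 7 members, 5 had positive scores and none passed over all genes. Whether the rise rested on RBM15 alone is therefore not settled. Several members were depleted in DMSO, so less growth under the drug was examined as another explanation. Against lists matched on dropout, the writer lay at percentile 99.92 or above. The matched medians were -0.25 and -0.44 against 0.95 and 0.65, so genes of like dropout did not rise. The matched lists again had weaker dropout in the other library (-0.50 against -0.70 and -0.42 against -0.50). Lists with stronger DMSO dropout had no positive median score. Their median scores were -0.67 for the cytosolic ribosome, -0.52 for RNA polymerase II and the spliceosome core and -0.56 for the proteasome. For the cytosolic ribosome and for RNA polymerase II and the spliceosome core, the library medians overlapped between the arms. The count filter also left only 52 of 71 ribosome genes. Those lists therefore do not decide the question. The matched lists argue against less growth as the whole cause. An effect of the drug on cells lacking the writer and a difference between sequencing lanes both stay open.

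The low correlation between the AZD4320 libraries (0.478) was set against depth and dominant guides. DMSO libraries thinned to the AZD4320 median count of 74 still correlated at 0.843. Without the top 1% of guides of either AZD4320 library the AZD4320 correlation was 0.473, against 0.857 for DMSO. Depth does not account for the gap, and neither do the top 1% of guides alone. Unevenness beyond the top 1% was not tested. Few surviving cells per guide under the drug may account for the gap, which no test here addresses.

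Whether partners of high or low scoring genes moved with them was also tested with camera. Adjusted over these 4 lists, the partners of PCGF1 and USP7 in PRC1.1 and those of CNOT10 and CNOT1 in CCR4-NOT both had an adjusted p of 0.479. The transfer RNA thiolation and Elongator partners of URM1 and CTU1 and the Mediator subunits named MED and a number, without MED23, CCNC and CDK8, both had an adjusted p of 0.381. Before adjustment, in the same order, limma's camera gave 0.414, 0.479, 0.186 and 0.19. None passed in the direction of its gene. Among the 3 splits of the 4 libraries into pairs, the split by treatment called 13 genes and the highest of the others 0, so 1 split gave as many as the real one, itself. With 3 splits no share under 0.05 is possible.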
